A study of Mus musculus with 23 samples.

How the data were processed

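Gene expression was measured by sequencing polyA RNA of sorted mouse spleen B cells. Cells were sorted into lysis buffer and frozen, and libraries were made with the SMART-seq v4 and Nextera XT kits. WT cells carried no guide RNA and were sorted as Thy1.1-negative, and KO cells carried 1 of 2 guides against Irf8 and were sorted as Thy1.1-positive. How the guide was delivered is not stated in the labels. Naive cells were sorted without CD11b, F4/80 and Thy1.2 and with B220. Activated B cells (B220 and GL7, no CD138) and plasmablasts (B220 or B220-intermediate, with CD138) were sorted after 72 hours with LPS (20 mg/ml as labelled), IL-5 (5 ng/ml) and IL-2 (20 ng/ml). Plasmablast is the name in the culture description, and the cell type label reads plasma cell. Groups were taken from the labels alone. They were naive WT and KO of each guide arm (3 libraries each), activated WT and KO (3 each), and plasmablast WT (2) and KO (3), and no column was left unmapped. Letters and m-numbers are not said in the labels to mark the same animal or culture. After group means were removed, libraries of the same letter or number correlated at r from -0.243 to 0.254, in 5 of 16 cases above the highest r with another letter or number. With 2 or 3 libraries per group this check is weak, and it does not exclude that a letter or number marks 1 animal or culture. The samples were treated as unpaired, and p-values measure the spread between these samples.

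The deposited values are RPKM, reads scaled to gene length and to the reads assigned to genes in each library, computed by the authors and rounded to 3 decimals, in 1 table for naive and 1 for cultured cells. Reads were aligned with STAR to mm10 per the submitters' processing notes. The version, the counting tool and the annotation are not stated there, nor is the rule by which the tables list detected genes. The 2 tables were made separately, so tests were run only within a table. Low values in each library were whole multiples of a common step (100% within 0.2 of a whole number), from which the reads assigned to genes were estimated. In plasmablast KO library 3 the listed genes held 72.3% of the RPKM mass times gene length, against at least 99.1% in the other libraries. The 50 highest genes of each library held 7.5% to 14.6% of its reads, taken as RPKM times gene length. Symbols that had been turned into dates, 15 per table, were restored from the gene identifier, and 1 gene of each had no symbol. Identifiers were found in a RefSeq gene table for 11540 naive and 10568 cultured genes, which also gave coordinates on GRCm38, the assembly called mm10. As counts are not analysed here, no interval for counting error is given, and the estimated reads bound the precision.

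Values were analysed as log2(RPKM + 1) in R 4.3.3 with limma 3.58.1, for genes at RPKM of 1 or more in at least 2 libraries of the table (10137 naive, 9986 cultured). Adding 1 makes differences of genes near or below 1 RPKM smaller than their ratios. Each table had 1 fit with a mean per group, and 10 contrasts were tested with limma's moderated two-sided test with a trend in the spread. The adjusted p is by Benjamini and Hochberg over all tested genes, and a gene is called at an adjusted p under 0.05. The difference for both guides is the mean of the 2 within-arm differences. Values after ± are SD between libraries, and values of both guides together include the difference between the arms.

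Gene lists were 26 programme lists and 8 lists of other cell types, tested with limma's camera with a preset correlation between genes of 0.01 and adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests a list's members against no change, stand beside it. Fry's p depends on the order of the groups in the design, which was alphabetical, and the numbers of lists it called were the same in another order tried. Of all calls of these lists over the 10 comparisons, that of MHC class II genes in WT plasmablasts against WT activated B cells held with an estimated correlation when all libraries were used (adjusted p = 0.0202), and without the 3 libraries left out below it did not (adjusted p = 0.262). Some genes are in more than 1 list. The programme lists were mature B cell identity, plasma cell programme, unfolded protein response and secretory pathway, MHC class I and MHC class II presentation, interferon-stimulated genes, interferon-gamma-inducible GTPases, interferon regulatory factors, marginal zone, follicular, transitional and immature, B-1 and age-associated and germinal centre B cells, B cell receptor signalling, Toll-like receptor and NF-kB, costimulation and activation, BCL2 family, trafficking receptors, immunoglobulin constant genes, DNA replication, G2/M and mitosis, MYC targets and ribosome biogenesis, glycolysis and mTORC1, oxidative phosphorylation, p53 targets, and immediate early and dissociation stress genes. The lists of other cell types were macrophages and monocytes, neutrophils, dendritic cells, T cells, natural killer cells, erythroid cells, platelets, and stromal and endothelial cells.

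Groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Irf8 and Thy1. For each KO comparison it adds the 8 called genes with the highest and the 8 with the lowest difference whose KO and WT libraries do not overlap, passing over variable segments and symbols of unnamed or small RNA genes. It adds 6 in each direction for WT plasmablasts against WT activated B cells, 5 in each direction for differences of differences, and up to 3 members of each list by smallest p. Some genes that the rule names are not reported here. Overlaps of calls were tested with Fisher's exact test, two-sided. Lists of genes higher or lower by at least 1 on the log2 scale in WT plasmablasts against WT activated B cells were tested in naive and activated KO cells and set beside 50 simulations of unchanged groups.

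Alternatives were a pseudocount of 0.1, no filter, a filter at RPKM of 5, quantile normalization, median-ratio scaling, the replicate letter or number as a block, only the groups of a contrast in the fit, and each library left out in turn. Chosen after seeing the data were library weights and fits without naive KO guide 1 library A, plasmablast KO library 3 or the m3 activated libraries, singly or as a set of 3, and the overlaps without Irf8 and Thy1 in the last of these. As no gene was called in the cultured KO comparisons with all libraries, the naming rule was applied there to the fit without those 3 libraries. The fits were tested on simulated data with 200 changed genes, taken from those with a mean log2(RPKM + 1) over 2. The noise was independent with 1 SD per gene, so the shares found do not cover genes at lower RPKM, an outlying library or exchanged samples. For a log2 difference of 1 they found 91% of changed genes in naive cells of both guides, 62% with guide 1, 30% in activated B cells and 15% in plasmablasts, and without the 3 libraries 92% and 90% in the latter. For a log2 difference of 2 these were 96%, 90%, 66% and 71%, and 100% and 99%. In WT plasmablasts against WT activated B cells they found 21% and 61%. Of the calls 1.1% to 8.9% were false.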

Results

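RNA was sequenced from mouse spleen B cells in which Irf8, the gene for a transcription factor of the interferon regulatory factor family, had been targeted with a guide RNA. KO cells were sorted as Thy1.1-positive and carried the guide, and WT cells were sorted as Thy1.1-negative and carried none. The 23 libraries fell into 8 groups. Naive B cells gave 12 libraries, with 3 WT and 3 KO in each of 2 arms, 1 arm per guide. Cultured cells gave 11 libraries, the KO ones of guide 1, from naive B cells stimulated for 72 hours with LPS, IL-5 and IL-2. These were activated B cells (3 WT, 3 KO), which had GL7 and no CD138 on their surface, and plasmablasts (2 WT, 3 KO), which had CD138. The third WT plasmablast library that the design text implies is not analysed here. There were 11548 genes in the naive table and 10574 in the cultured one, and 10178 genes were in both. The number of reads assigned to genes, estimated from the smallest steps between values, was 14500000 to 22200000 per naive library. It was 4300000 to 26900000 per cultured library except plasmablast KO library 3, with 51000. In that library 1984 genes were listed at 0, and its median correlation with the other cultured libraries was 0.477, against 0.944 to 0.968 for the others. Naive KO guide 1 library A had 1405 genes listed at 0 and a median correlation of 0.87, against 66 to 291 genes and 0.959 to 0.979 in the other naive libraries.

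Irf8 transcripts were measured in all KO libraries, and in naive cells each KO library held less than each WT library. The data hold RNA and no protein, so they do not show how much IRF8 protein the KO cells kept. Irf8 (Entrez 15900, chromosome 8, 120736358 to 120756694 on GRCm38) was at 69.9 ± 9.35 RPKM (SD, n = 3) in naive KO cells of guide 1 and 95.7 ± 2.35 (SD, n = 3) in their WT cells. With guide 2 it was at 49.6 ± 1.76 (SD, n = 3) in KO and 85.4 ± 4.86 (SD, n = 3) in WT. In activated B cells Irf8 was at 69.2 and 68.1 RPKM in the KO libraries m1 and m2 and at 108 and 93.6 in the WT libraries m1 and m2. The m3 libraries went the other way, with 92.4 in the library labelled KO and 60 in the library labelled WT. Plasmablasts held less Irf8, 21.0 ± 3.37 in KO (SD, n = 3) and 21.1 ± 4.99 in WT (SD, n = 2). Thy1 (Entrez 21838, chromosome 9, 44043384 to 44048579 on GRCm38), the gene of the marker on which KO cells were sorted, was at 11.1 ± 1.94 RPKM in naive KO cells of guide 1 (SD, n = 3) and 17.3 ± 4.63 in those of guide 2 (SD, n = 3). Naive WT cells held at most 0.052 RPKM of Thy1, except WT library A of the guide 1 arm at 4.93. Thy1 in the activated KO libraries m1 and m2 was at 21.9 and 27.8 RPKM, and the WT libraries m1 and m2 were at 0.013 and 0.055. At m3 the library labelled KO held 0.093 and the library labelled WT held 25.7. Plasmablast KO libraries held 32.8, 40.7 and 35.9 RPKM of Thy1 and WT libraries 0.057 and 0.142.

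**Figure D1:**
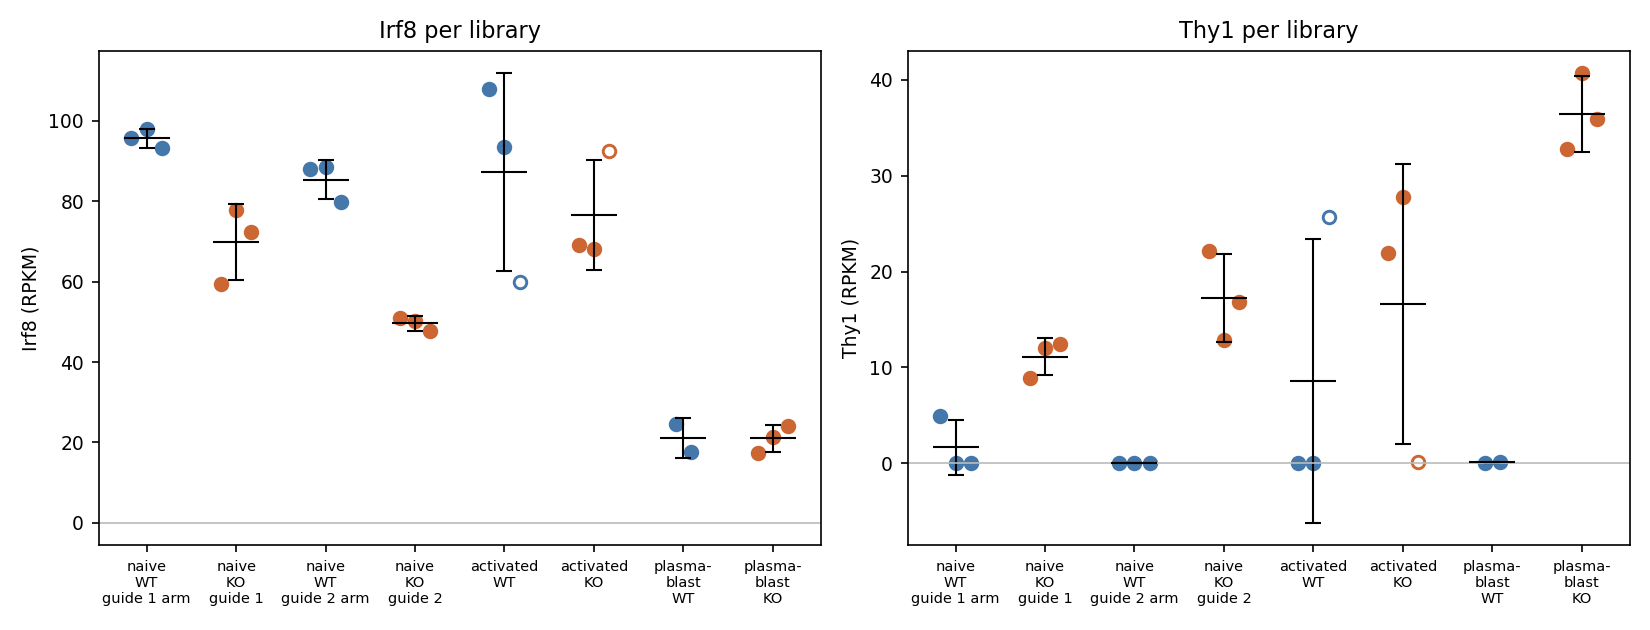
Irf8 and Thy1 in RPKM (vertical axes) in each library of the 8 groups, with the group mean and SD; open circles are the m3 activated B cell libraries. Thy1 of the open circles is at 25.7 in the library labelled WT and 0.093 in the library labelled KO, against the labels.

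Naive KO and WT B cells were compared, averaged over both guides, to ask which genes differ with the Irf8 guides before any stimulation. KO cells also differed from WT cells in carrying a guide at all and in the Thy1.1 sort. No group carried a guide against another gene, so effects of Irf8 loss cannot be told apart from these in any KO comparison here. Of the genes of marginal zone B cells, the innate-like B cells at the border of the spleen's white pulp, 7 of 17 rose, and 3 of 11 follicular and 2 of 8 transitional B cell genes fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.217, 0.277 and 0.277). S1pr3, the sphingosine-1-phosphate receptor of marginal zone B cells, was at 114 ± 38.2 RPKM in KO (SD, n = 6) and 27.8 ± 13.6 in WT (SD, n = 6), a log2 difference of 2.04 (adjusted p = 0.00313). Cr2, the complement receptor CD21, rose by 1.16 on the log2 scale to 228 ± 35.4 RPKM from 108 ± 41.7 (adjusted p = 0.00493). Fcer2a, the follicular marker CD23, fell by 1.10 to 179 ± 62.8 RPKM from 367 ± 54.5 (adjusted p = 0.0211). Irf8 itself fell by 0.61 to 59.7 ± 12.6 from 90.6 ± 6.57 RPKM (adjusted p = 0.00412), and Thy1 rose by 3.42 to 14.2 ± 4.64 from 0.838 ± 2.0 (adjusted p = 0.00313).

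Of the 17 measured members of the marginal zone list, 7 rose, 10 were not called and 16 had a positive difference. Adjusted over the list alone, 15 rose. The median log2 difference was 0.85 (adjusted p = 1.26e-17, and adjusted p = 0.217 with an estimated correlation). Dtx1, a target of Notch signalling, was at 106 ± 36.3 RPKM in KO and 38.8 ± 16.3 in WT (log2 difference 1.46). Pdia4, a protein disulfide isomerase of the endoplasmic reticulum, was at 491 ± 105 and 269 ± 47.8 (0.85). Of 11 follicular genes 3 fell (median -0.35; adjusted p = 0.000528, and adjusted p = 0.277 with an estimated correlation). Adjusted over the list alone, 5 fell and 1 rose. Klf2, a transcription factor of quiescence and trafficking, fell from 304 ± 32.5 to 201 ± 43.0 RPKM, and Vpreb3, a protein that binds nascent immunoglobulin chains in immature B cells, from 78.1 ± 20.7 to 32.1 ± 12.5. Of 8 transitional and immature B cell genes 2 fell, Vpreb3 and the transcription factor Myb (2.1 ± 1.67 from 7.16 ± 3.41 RPKM), and 3 fell adjusted over the list alone (median -1.02; adjusted p = 0.000665, and adjusted p = 0.277 with an estimated correlation). In the list of B-1 and age-associated B cells no member of 13 was called over all genes and 3 rose adjusted over the list alone (median 0.35; adjusted p = 0.0116, and adjusted p = 0.217 with an estimated correlation).

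**Figure D2:**
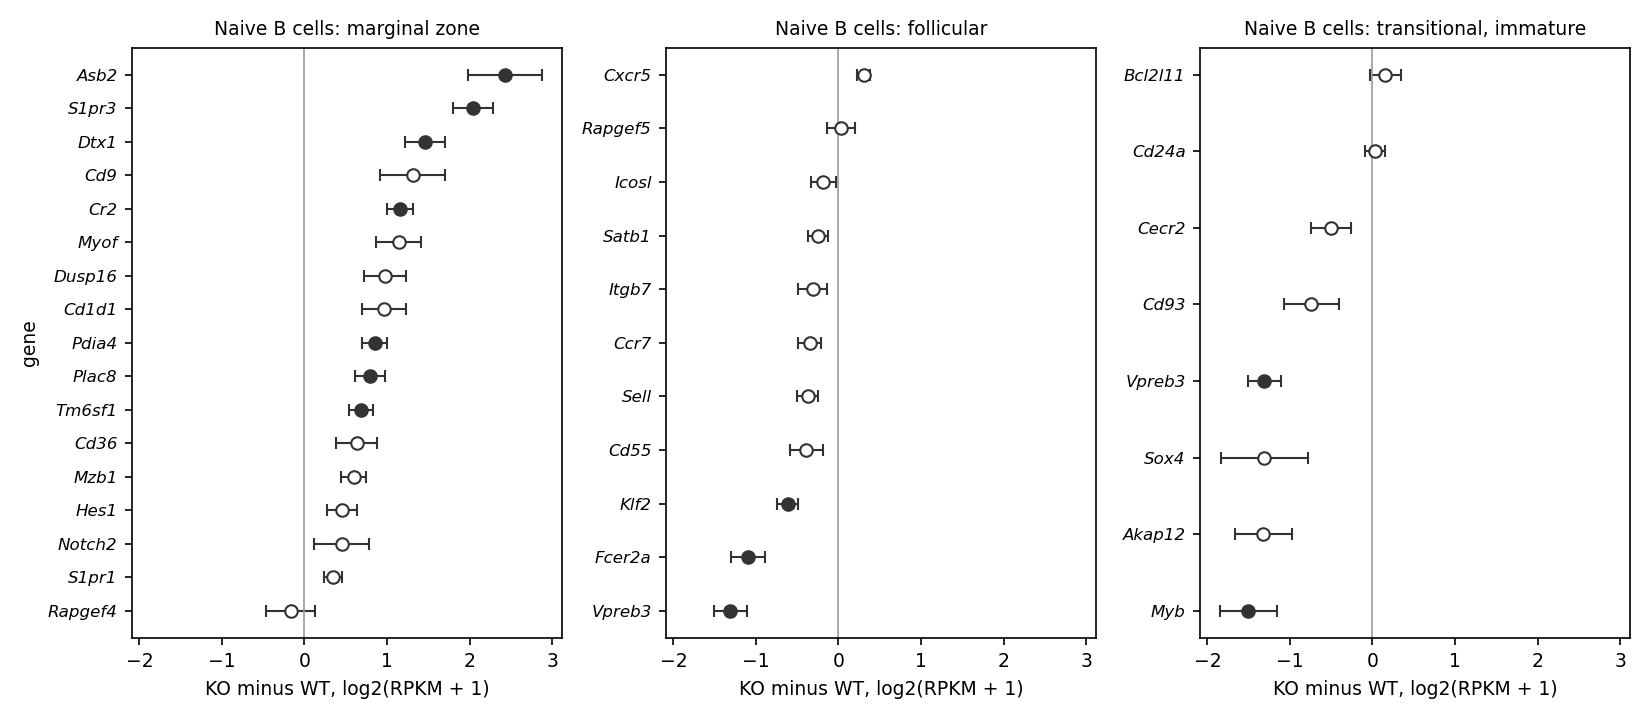
Log2 difference in log2(RPKM + 1) between KO and WT naive B cells of both guides (horizontal axis), with its standard error, for the measured members of 3 fixed lists; filled points are called. Marginal zone members lie above 0 in 16 of 17 cases, with a median of 0.85, and the follicular and transitional medians are -0.35 and -1.02.

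The genes with the highest differences were taken among those whose KO libraries all lay above all WT libraries. Besides Thy1 and S1pr3 these were Gpr34, a receptor for lysophosphatidylserine (30.2 ± 7.85 RPKM in KO, 4.87 ± 3.9 in WT, log2 difference 2.67), Tmem121 (1.93), Ifit1 (1.91), Pla2g7, a phospholipase that degrades platelet-activating factor (1.79), Rgs10, a regulator of G protein signalling (1.62), and Trem1, an activating receptor of myeloid cells (1.56). The genes that fell most by the same rule were Wfdc17 (1.76 ± 1.73 RPKM in KO, 15.2 ± 4.71 in WT, log2 difference -2.73), the kynurenine monooxygenase Kmo (8.17 ± 5.1 and 33.4 ± 5.21, -2.29), Scimp, an adaptor of antigen-presenting cells (4.86 ± 2.94 and 19.4 ± 3.07, -2.05), and Fcgrt, the heavy chain of the neonatal Fc receptor (2.94 ± 1.82 and 11 ± 1.81, -1.79). Phf11a (-1.67), the pseudokinase Trib2 (-1.49), Sdc1, the gene of CD138 (-1.49), and Diras2 (-1.46) followed. Sdc1 was at 0.399 ± 0.465 RPKM in KO and 2.85 ± 0.845 in WT naive cells.

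The interferon-stimulated list as a whole was not called (33 members, median 0.00; adjusted p = 0.601), but 4 members rose, and adjusted over the list alone 5 rose and 2 fell. Isg15, a ubiquitin-like protein induced by interferon, was at 28.5 ± 10.6 RPKM in KO and 9.86 ± 2.41 in WT. Ifit1, an interferon-induced RNA-binding protein, was at 19.0 ± 6.62 and 4.36 ± 1.93, and Oas1a, an oligoadenylate synthetase, at 14.9 ± 2.81 and 7.02 ± 2.03. The interferon-gamma-inducible GTPases were called higher (13 members, 1 rose, 7 rose adjusted over the list alone, median 0.42; adjusted p = 0.000308, and adjusted p = 0.277 with an estimated correlation), with Gbp2 at 29.0 ± 3.67 RPKM in KO and 17.2 ± 3.29 in WT. Proliferation genes were called lower. All 19 G2/M genes had a negative difference, none was called, and none was called adjusted over the list alone (median -0.58; adjusted p = 7.65e-05, and adjusted p = 0.611 with an estimated correlation). Of 20 DNA replication genes 1 fell, the helicase gene Mcm5 (11.1 ± 2.86 RPKM in KO, 18.9 ± 2.76 in WT), also the 1 that fell adjusted over the list alone (median -0.27; adjusted p = 0.000665, and adjusted p = 0.277 with an estimated correlation). MYC targets and ribosome biogenesis were called higher without a called member (21 members, 0 adjusted over the list alone, median 0.15; adjusted p = 0.00587, and adjusted p = 0.644 with an estimated correlation). Of 17 immediate early genes 1 fell, the transcription factor gene Egr1 (8.18 ± 3.0 from 16.6 ± 1.89 RPKM), and 4 fell adjusted over the list alone (median -0.17; adjusted p = 0.0453, and adjusted p = 0.611 with an estimated correlation). Neither the MYC nor the immediate early list was called without naive KO guide 1 library A.

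Lists that were not called still held called members. In the BCL2 family (12 members; adjusted p = 0.184) 3 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone. The pro-apoptotic Bid was at 46.2 ± 7.28 RPKM in KO and 28.4 ± 3.7 in WT, the anti-apoptotic Bcl2a1d at 58.0 ± 13.5 and 30.5 ± 8.81, and the anti-apoptotic Mcl1 fell to 269 ± 18.3 from 349 ± 39.5. In the mature B cell list (20; adjusted p = 0.325) Cr2 rose, Fcer2a fell, and Bach2, a repressor of the plasma cell programme, fell to 6.93 ± 2.46 from 17.5 ± 3.54 RPKM. Adjusted over that list alone, 3 rose and 3 fell. In the plasma cell list (20; adjusted p = 0.184) Sdc1 and Txndc5, a disulfide isomerase, fell, the latter to 39.9 ± 8.38 from 61.8 ± 8.07 RPKM, and 1 rose and 2 fell adjusted over the list alone. Among germinal centre genes (10; adjusted p = 0.106) Bcl6 fell to 15.9 ± 2.06 from 24.1 ± 3.31 RPKM, and 3 fell adjusted over the list alone. Among B cell receptor genes (24; adjusted p = 0.91) Cr2 and Nfatc1 rose, the latter, a calcium-dependent transcription factor, to 96.0 ± 19.0 from 61.8 ± 6.03 RPKM, and 3 rose and 1 fell adjusted over the list alone. Among costimulation genes (18; adjusted p = 0.979) the cytokine subunit Ebi3 rose to 29.0 ± 5.94 from 16.3 ± 3.68 RPKM and the activation marker Cd83 fell to 101 ± 6.54 from 130 ± 6.02, with 2 higher and 2 lower adjusted over the list alone. Among trafficking receptors (17; adjusted p = 0.986) 2 rose and 1 fell, and 4 rose and 5 fell adjusted over the list alone. Ackr3, a scavenging receptor for CXCL12, rose to 16.1 ± 10.6 from 3.18 ± 2.8 RPKM and S1pr4 fell to 23 ± 4.55 from 38.5 ± 5.76. In the unfolded protein response list (27; adjusted p = 0.629) Pdia4 rose and Herpud1 fell to 43.3 ± 2.35 from 58.5 ± 4.63 RPKM.

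Further lists without a call were glycolysis and mTORC1 (24 members; adjusted p = 0.073), MHC class I presentation (19; 0.325), interferon regulatory factors (7; 0.463), MHC class II presentation (17; 0.647), oxidative phosphorylation (24; 0.93), p53 targets (18; 0.979) and Toll-like receptor and NF-kB genes (23; 0.986). Each of these had 0 called members, also adjusted over the list alone. The list of immunoglobulin constant genes had 1 measured member, the joining chain gene Jchain (adjusted p = 0.986). The constant genes themselves in that list were thus not tested in naive cells. No list of another cell type was called in naive cells. The adjusted p was 0.253 for natural killer cells (8 members), 0.463 for T cells (3), 0.93 for erythroid cells (5) and dendritic cells (3), 0.952 for macrophages and monocytes (10) and 0.986 for stromal and endothelial cells (1). The lists of neutrophils and platelets had no measured member. Prf1, the perforin gene of the natural killer list, rose to 3.97 ± 1.18 from 1.11 ± 0.696 RPKM, and 1 member of that list rose and 1 fell adjusted over the list alone.

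In all, limma called 191 of 10137 tested genes, 104 higher and 87 lower in KO, of which 85 differed by at least 1 on the log2 scale. Unadjusted p was under 0.05 for 1289 genes, against 507 by chance. The count moved by over 1.5 times without each of 10 libraries. It was 387 and 384 without KO guide 1 A and B, 80 and 93 without KO guide 2 A and B, 107, 100 and 80 without WT A, B and C of the guide 1 arm, and 111, 73 and 84 without WT A, B and C of the guide 2 arm. Irf8, Thy1, S1pr3, Cr2, Gpr34, Wfdc17, Vpreb3 and Bach2 kept their call in each of these fits. Calls were lost in 12 of 19 alternatives for Myb and Egr1, 11 for Kmo, and 10 for Klf2 and Trib2. They were lost in 8 for Bcl6, Fcgrt and Nfatc1, 7 for Txndc5, and 6 for Fcer2a, Ackr3, Ebi3 and Rgs10. Fewer alternatives lost those of Bcl2a1d (5), Cd83, Mcm5, Pla2g7, S1pr4 and Scimp (4 each), Mcl1 (2), and Gbp2 and Phf11a (1 each).

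Each guide was also compared with its own WT cells, to ask whether 2 different guides gave the same change. Ifit1 rose with both. So did Thy1, but as the marker of the sort it does not bear on that question. Ifit1 was at 18.9 ± 9.01 RPKM in KO and 5.78 ± 1.71 in WT with guide 1 (SD, n = 3 each; log2 difference 1.49, adjusted p = 0.0417), and at 19.2 ± 5.33 and 2.95 ± 0.612 with guide 2 (2.33, adjusted p = 0.0268). Thy1 rose by 2.71 with guide 1 (adjusted p = 0.0337) and by 4.13 with guide 2 (adjusted p = 0.0268). Irf8 fell by 0.77 with guide 2 (adjusted p = 0.0427). With guide 1 its difference of -0.46 was not called (adjusted p = 0.0703), although all 3 KO libraries lay below all 3 WT libraries. The marginal zone list was called higher with each guide. With guide 1, 5 of 17 members rose, 14 adjusted over the list alone (median 1.02; adjusted p = 6.15e-14, and adjusted p = 0.419 with an estimated correlation). With guide 2 none rose, and 6 rose adjusted over the list alone (median 0.74; adjusted p = 1.45e-13, and adjusted p = 0.244 with an estimated correlation). The transitional list was called lower with each (medians -1.26 and -0.73; adjusted p = 0.0021 and 0.0285, and adjusted p = 0.419 and 0.397 with an estimated correlation), as was the follicular list (medians -0.39 and -0.31; adjusted p = 0.0103 and 0.00075, and adjusted p = 0.557 and 0.384 with an estimated correlation). Interferon-stimulated genes were called higher with guide 2 (33 members, 1 rose, 4 adjusted over the list alone, median 0.14; adjusted p = 0.00188, and adjusted p = 0.384 with an estimated correlation).

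In total limma called 113 genes with guide 1 (60 higher, 53 lower) and 3 with guide 2 (2 higher, 1 lower). Across 10137 genes the differences of the 2 guides correlated with r = 0.413 (Spearman's rho 0.291; genes are not independent replicates), and 110 of the 113 guide 1 calls had the same sign with guide 2. Thy1 and Ifit1 were higher with both guides. Without the sorted marker Thy1 and Irf8, the shared gene was Ifit1, against 0.00582 by chance (Fisher's exact test, two-sided, p = 0.00582). For the difference between the guides in KO against WT limma called 0 genes (479 at an unadjusted p under 0.05; smallest adjusted p 0.918). The guide 1 count was 0 without WT library C, 28 and 27 without WT A and B, and 242 and 371 without KO A and B, and the guide 2 count was 0 without any of its 6 libraries and 35 without KO guide 1 A. Without that library 19 calls were shared by the guides.

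WT cells of the 2 naive arms, labelled as carrying no guide, were compared to show how far the arms differ without a knockout. Thy1 was at 4.93 RPKM in WT library A of the guide 1 arm, against at most 0.052 in the other naive WT libraries. The called genes were X- and Y-linked genes of sex, named here after their values were seen. The Y-linked Eif2s3y, Ddx3y, Uty and Kdm5d were higher in the guide 2 arm by 5.22, 4.58, 2.42 and 2.17 on the log2 scale (adjusted p = 2.09e-09, 5.35e-08, 0.000192 and 0.00109), and Xist, the RNA that silences an X chromosome in females, was lower (log2 difference -2.20; adjusted p = 0.00102). KO and WT libraries within an arm shared the pattern. The marginal zone list was higher in WT cells of the guide 2 arm (17 members, 0 called, 2 adjusted over the list alone, 16 positive, median 0.40; adjusted p = 1.12e-07, and adjusted p = 0.405 with an estimated correlation). G2/M genes (median -0.60; adjusted p = 6.97e-07, and adjusted p = 0.514 with an estimated correlation), immediate early genes (-0.19; 0.000684, and adjusted p = 0.405 with an estimated correlation), transitional genes (-0.31; 0.00889, and adjusted p = 0.405 with an estimated correlation) and DNA replication genes (-0.17; 0.0199, and adjusted p = 0.464 with an estimated correlation) were lower. In total limma called 5 genes.

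KO and WT activated B cells were compared to ask what differs with the Irf8 guide after stimulation. With all 6 libraries no gene was called, and Thy1 was at 16.6 ± 14.6 RPKM in KO (SD, n = 3) and 8.6 ± 14.8 in WT (SD, n = 3), with the m3 libraries against their labels. Without the m3 libraries and plasmablast KO library 3, a choice made after seeing the data, 6 of 30 interferon-stimulated genes and 3 of 22 genes of the plasma cell programme rose in KO. The calls of both lists were lost with an estimated correlation (adjusted p = 0.334 each). Isg15 rose to 122 ± 9.37 RPKM from 75.9 ± 2.45 (SD, n = 2 each; log2 difference 0.68, adjusted p = 0.0139), Irf7, a regulator of interferon genes, to 22.5 ± 4.5 from 11.3 ± 0.156 (0.92, adjusted p = 0.0105), and Tnfrsf17, the plasma cell receptor BCMA, to 1.68 ± 0.162 from 0.234 ± 0.0205 (1.12, adjusted p = 0.0235). Thy1, the marker of the sort, was at 24.9 ± 4.13 and 0.034 ± 0.0297 RPKM (4.64, adjusted p = 7.8e-09). Irf8 was at 68.6 ± 0.78 and 101 ± 10.5 RPKM, which was not called (-0.55, adjusted p = 0.126). As the m3 libraries, in which both genes went against the labels, were left out after seeing the data, neither difference is an independent test. All values in this and the next 2 paragraphs come from the libraries m1 and m2 unless stated.

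Of 30 interferon-stimulated genes 6 rose, 11 adjusted over the list alone (median 0.21; adjusted p = 2.15e-10, and adjusted p = 0.334 with an estimated correlation), with Rtp4 at 5.83 ± 0.378 RPKM in KO and 1.77 ± 0.221 in WT. Of 12 interferon-gamma-inducible GTPases 2 rose, 3 adjusted over the list alone (median 0.25; adjusted p = 0.00132, and adjusted p = 0.334 with an estimated correlation), namely Tgtp1 (7.88 ± 0.175 from 3.18 ± 0.996) and Tgtp2 (10.6 ± 0.629 from 3.97 ± 0.668). Of 22 plasma cell genes 3 rose, 11 adjusted over the list alone (median 0.48; adjusted p = 4.1e-11, and adjusted p = 0.334 with an estimated correlation). Besides Tnfrsf17 these were Fkbp11, a chaperone of the secretory pathway (42.8 ± 0.238 from 21.8 ± 7.93), and Ell2, an elongation factor for secreted immunoglobulin transcripts (39.8 ± 3.29 from 26.4 ± 3.49). All 27 unfolded protein response genes had a positive difference, 0 were called and 3 rose adjusted over the list alone (median 0.29; adjusted p = 2.47e-09, and adjusted p = 0.397 with an estimated correlation). MYC targets and ribosome biogenesis were called lower (21 members, 0 over all genes, 14 adjusted over the list alone, median -0.38; adjusted p = 1.71e-11, and adjusted p = 0.334 with an estimated correlation), as was DNA replication (22 members, 0 adjusted over the list alone, median -0.19; adjusted p = 1.49e-05, and adjusted p = 0.432 with an estimated correlation). The marginal zone list was called higher (16 members, 0 over all genes, 3 adjusted over the list alone, median 0.38; adjusted p = 0.000398, and adjusted p = 0.334 with an estimated correlation). So was the T cell list through its 2 measured members Lck (4.89 ± 0.215 and 3.57 ± 0.0537) and Cd28 (1.1 ± 0.029 and 0.29 ± 0.0127), neither called over all genes and 1 adjusted over the list alone (median 0.53; adjusted p = 0.015, and adjusted p = 0.334 with an estimated correlation). Cd28 is also in the plasma cell list.

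The highest other differences were those of Nox1, a NADPH oxidase (4.58 ± 1.55 RPKM in KO, 0.662 ± 0.449 in WT, log2 difference 1.75), the glutamate transporter Slc1a1 (1.55), Ifit1bl1 (1.46), the tetraspanin Tspan15 (1.41) and C4bp, a complement inhibitor (1.20). Dkk3, a secreted protein of the Dickkopf family, fell most (3.71 ± 0.595 from 11.4 ± 2.42, log2 difference -1.39), followed by Mpeg1, the pore-forming perforin-2 (-1.25), the RNase P RNA gene Rpph1 (-0.94), the trafficking receptor Gpr15 (-0.93), Kmo (5.26 ± 0.806 from 10.7 ± 1.05, -0.90), Dennd4b (-0.73) and the nucleoporin gene Nup210 (-0.55). Among other lists, Nuggc, a GTPase of germinal centre B cells, rose (15.3 ± 1.36 from 8.64 ± 2.38), as did the phosphatase gene Dusp1 (10.2 ± 1.58 from 5.5 ± 1.2), and Ifi30, a lysosomal thiol reductase of antigen processing, fell (67.1 ± 0.673 from 96.7 ± 2.75). With all libraries none of these was called (adjusted p = 1 each). The difference was then 0.67 for Nox1, 0.45 for Slc1a1, -0.44 for Dkk3, -0.41 for Gpr15, -0.15 for Kmo, -0.01 for Ifi30, 0.22 for Isg15 and 0.17 for Fkbp11.

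**Figure D3:**
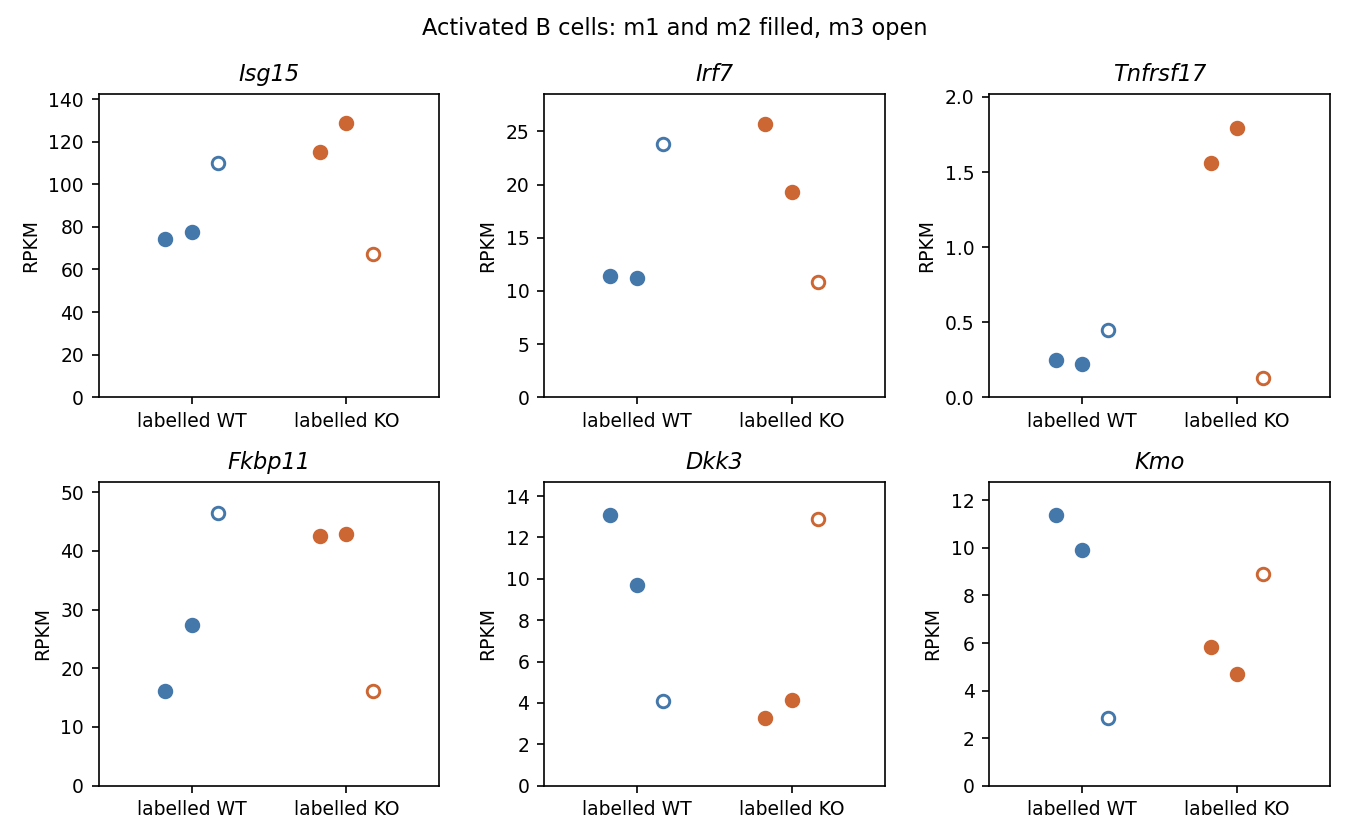
RPKM (vertical axes, from 0) of 6 genes in each activated B cell library by its label, with m1 and m2 filled and m3 open. In m3 Isg15 is at 110 in the library labelled WT and 67.2 in the library labelled KO, and Dkk3 is at 4.07 and 12.9, the reverse of m1 and m2.

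With all libraries limma called 0 genes in activated B cells (2 at an unadjusted p under 0.05, against 499 by chance), and the 1 list called was DNA replication (22 members, 0 adjusted over the list alone, median -0.08; adjusted p = 0.00357, and adjusted p = 0.977 with an estimated correlation). Without the 3 libraries it called 70 of 9861 genes, 61 higher and 9 lower, and 1185 had an unadjusted p under 0.05. Without the m3 libraries alone the count was 1.

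KO and WT plasmablasts were compared with the same question for the CD138-positive cells. Without plasmablast KO library 3 and the m3 activated libraries, Il10, the gene of an anti-inflammatory cytokine, rose in KO and Vpreb3 fell. Il10 was at 29.5 ± 5.93 RPKM in KO and 9.26 ± 1.11 in WT (SD, n = 2 each; log2 difference 1.56, adjusted p = 0.00127). Emb, a membrane glycoprotein of the immunoglobulin family, was at 7.01 ± 0.62 and 2.2 ± 0.117 (1.32, adjusted p = 0.0051), and the anti-apoptotic Bcl2a1b at 8.26 ± 0.945 and 3.59 ± 0.883 (1.02, adjusted p = 0.047). Vpreb3 fell to 87.7 ± 0.511 from 141 ± 0.535 RPKM (-0.68, adjusted p = 0.047), and Thy1 was at 36.7 ± 5.63 and 0.0995 ± 0.0601 (5.09, adjusted p = 2.38e-09). Irf8 was at 19.5 ± 2.8 and 21.1 ± 4.99 RPKM (-0.10, adjusted p = 0.992).

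Called lists in these plasmablasts moved by small amounts. G2/M genes were lower (20 members, 0 called, 0 adjusted over the list alone, median -0.23; adjusted p = 8.46e-11, and adjusted p = 0.368 with an estimated correlation), as was DNA replication (22, 0 called, 0 adjusted over the list alone, -0.13; 3.62e-05, and adjusted p = 0.437 with an estimated correlation). The BCL2 family was higher (13 members, 1 rose, 4 adjusted over the list alone, 0.31; 0.000306, and adjusted p = 0.368 with an estimated correlation), as were p53 targets (22, 0 called, 1 adjusted over the list alone, 0.23; 6.78e-06, and adjusted p = 0.368 with an estimated correlation) and mature B cell genes (20, 0 called, 3 adjusted over the list alone, 0.12; 0.000306, and adjusted p = 0.368 with an estimated correlation). Of the transitional list 1 of 8 members fell, Vpreb3, and 1 rose and 2 fell adjusted over the list alone (-0.26; 0.00563, and adjusted p = 0.368 with an estimated correlation). The unfolded protein response list was called lower with a median of -0.06 (adjusted p = 0.00805, and adjusted p = 0.584 with an estimated correlation), which was 0.01 after quantile normalization.

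Without the 3 libraries limma called 7 genes, 6 higher and 1 lower, with 588 at an unadjusted p under 0.05. Of the calls not named above 1 is an unannotated Gm gene. These calls also needed the m3 activated libraries left out, which share the estimate of spread. Without plasmablast KO library 3 alone limma called 0 genes (231 at an unadjusted p under 0.05), and with library weights 0 (321 at an unadjusted p under 0.05). With all libraries it called 0 genes (85 at an unadjusted p under 0.05; smallest adjusted p 0.609), and Il10 and Bcl2a1b had the opposite sign (-0.08 and -0.05), Il10 being listed at 0 in KO library 3. Of the 6 lists called lower with all libraries none was called with an estimated correlation (adjusted p = 0.887 for each), and the median of all genes was -0.121, against -0.023 after quantile normalization. The lists were G2/M (median -0.70; adjusted p = 2.15e-05), oxidative phosphorylation (-0.50; 0.000117), unfolded protein response (-0.56; 0.000378), MHC class I (-0.40; 0.00796), DNA replication (-0.44; 0.012) and plasma cell programme (-0.47; 0.0157). After quantile normalization these medians were, in the same order, -0.47, -0.14, -0.12, -0.16, -0.25 and -0.13.

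The difference between plasmablasts and activated B cells in KO against WT was tested itself. When the 3 libraries were left out, Spib, a transcription factor of B cell identity, was relatively higher in KO plasmablasts (log2 difference 1.45) and Rgcc, a regulator of the cell cycle, was relatively lower (-1.03; adjusted p = 0.0382 for each). Spib was at 1.45 and 1.54 RPKM in KO plasmablasts 1 and 2, and at 0.464 and 0.281 in WT, while activated KO libraries m1 and m2 held 31.5 and 39.3 and WT 55.6 and 51.0. Rgcc was at 176 and 171 RPKM in KO and 169 in each WT plasmablast library, and at 50.9 and 48.2 in activated KO and 24.0 and 22.2 in activated WT libraries m1 and m2. Lists of the plasma cell programme (22 members, 0 called, 0 adjusted over the list alone, median -0.53; adjusted p = 2.95e-11) and the unfolded protein response (27, 0 called, 0 adjusted over the list alone, -0.37; 1.15e-11) were relatively lower, and MYC targets (21, 0 called, 9 adjusted over the list alone, 0.46; 2.29e-10) relatively higher (adjusted p = 0.329 for each with an estimated correlation). Among 32 lists 14 were called. With all libraries limma called 0 genes (10 at an unadjusted p under 0.05), and without the 3 libraries it called 3 (752 at an unadjusted p under 0.05).

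WT plasmablasts were compared with WT activated B cells to describe the change from the activated to the secreting stage. Sdc1, the gene of the sorted marker CD138, was at 30.8 ± 4.71 RPKM in plasmablasts (SD, n = 2) and 0.329 ± 0.129 in activated cells (SD, n = 3; log2 difference 4.58, adjusted p = 0.0202). Irf8 fell to 21.1 ± 4.99 from 87.3 ± 24.8 RPKM (-1.98, adjusted p = 0.0156). Spib (0.373 ± 0.129 from 45.1 ± 14.4) and the chemokine receptor Ccr7 (0.964 ± 0.205 from 60.3 ± 21.1) fell by 5.02 and 4.91 on the log2 scale. The activated group includes the m3 library labelled WT, in which Thy1 was at 25.7 RPKM.

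Besides Sdc1 the highest genes were Gpr160 (10 ± 0.648 RPKM from 0.847 ± 0.338), Rgcc (169 ± 0.479 from 28.9 ± 10.1), the protease inhibitor Slpi (666 ± 51.9 from 134 ± 71.3), Wipi1, an autophagy protein (9.62 ± 0.26 from 1.84 ± 0.723), and the ectonucleotidase Entpd1 (17.4 ± 0.963 from 4.04 ± 0.659). Further genes that fell were the inhibitory receptor Cd22 (1.03 ± 0.513 from 56.6 ± 27.4), Gbp2 (0.98 ± 0.694 from 44.5 ± 8.39), Ms4a4c (1.86 ± 1.07 from 58.5 ± 21.5), Klf2 (2.53 ± 2.17 from 45.8 ± 14.7), the transcriptional repressor Zbtb32 (5.52 ± 1.21 from 91.9 ± 39.0) and Cd83 (8.4 ± 1.91 from 89.7 ± 32.5). Of 17 MHC class II genes 4 fell, and 10 fell and 1 rose adjusted over the list alone (median -0.89; adjusted p = 4.56e-07, and adjusted p = 0.0202 with an estimated correlation). With the 3 libraries left out, this list had an adjusted p = 0.262 with an estimated correlation. They included Ciita, the master regulator of class II genes (0.387 ± 0.0849 from 13.1 ± 5.02), H2-DMb1 (5.37 ± 1.89 from 46.4 ± 10) and H2-DMb2 (12.3 ± 1.66 from 112 ± 21.6), subunits of the peptide-loading factor. Of 20 mature B cell genes 7 fell, 11 adjusted over the list alone (median -1.51; adjusted p = 6.43e-12, and adjusted p = 0.128 with an estimated correlation), and of 11 follicular genes 4 fell, 5 adjusted over the list alone (-1.28; 8.87e-06, and adjusted p = 0.128 with an estimated correlation). Of 22 plasma cell genes 1 rose, Sdc1, and 10 rose adjusted over the list alone (median 1.10; adjusted p = 3.03e-12, and adjusted p = 0.228 with an estimated correlation). Of 27 unfolded protein response genes 26 had a positive difference and 0 were called, also adjusted over the list alone (0.88; 1.43e-10, and adjusted p = 0.32 with an estimated correlation).

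In total limma called 176 of 9986 genes, 33 higher and 143 lower in WT plasmablasts. The median of all genes was -0.117, which was -0.002 with median-ratio scaling (58 higher, 125 lower) and 0.012 with quantile normalization (157 higher, 212 lower). No gene was called without WT plasmablast library 2 (23 without library 1, 28 and 27 without the activated WT libraries m1 and m2), and 3303 were called without plasmablast KO library 3. The same comparison in KO cells called 344 genes, 77 higher and 267 lower (255 and 310 with quantile normalization; 111 and 236 with median-ratio scaling). The activated KO group includes the m3 library labelled KO, in which Thy1 was at 0.093 and Irf8 at 92.4 RPKM. Irf8 fell to 21.0 ± 3.37 RPKM in KO plasmablasts (SD, n = 3) from 76.5 ± 13.7 in activated KO cells (SD, n = 3; log2 difference -1.81, adjusted p = 0.0117; -1.77, adjusted p = 2.84e-06 without the 3 libraries), Spib to 0.997 ± 0.865 from 42.2 ± 12.4 and H2-DMb2 to 14.4 ± 1.12 from 106 ± 9.38, while Sdc1 rose to 21.9 ± 16.5 from 0.583 ± 0.182. Of 17 MHC class II genes 8 fell, 11 adjusted over the list alone (median -1.11; adjusted p = 5.92e-05, and adjusted p = 0.0608 with an estimated correlation), and the median of all genes was -0.215 (0.010 with quantile normalization). The count was 3033 without plasmablast KO library 3, 201 and 165 without plasmablast KO libraries 1 and 2, and 54, 22 and 57 without the activated KO libraries m1, m2 and m3.

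Genes changed in naive KO cells were compared with those changed in cultured KO cells. With the 3 libraries left out 8 genes were higher in KO in both naive and activated B cells, Thy1, Isg15, Oas1a, Rgs10, Tspan15, Emb, Ddx60 and Insl6. Without the sorted marker Thy1 and Irf8 there were 7, against 0.406 by chance (Fisher's exact test, two-sided, p = 1.3e-07). Fisher's test takes genes as independent, and Isg15 and Oas1a are both interferon-stimulated genes, so the p-values of these overlaps may be too small. Both comparisons also set cells with a guide, sorted by Thy1.1, against cells without one. Kmo was lower in both (Fisher's exact test, p = 0.0468) and 1 gene went opposite ways. The genes Emb, Ddx60 and Insl6 are named here after their values were seen. Thy1, Emb and Bcl2a1b were higher and Vpreb3 lower in both naive cells and plasmablasts (Fisher's exact test, p = 0.000477 and 0.00795 without Thy1 and Irf8), and Thy1 and Emb were higher in both activated B cells and plasmablasts (p = 0.0301 without Thy1 and Irf8). Across 9315 genes the differences in naive cells correlated with those in activated B cells at r = 0.165 and with those in plasmablasts at 0.187, and across 9861 genes the latter 2 correlated at 0.179 (genes are not independent replicates). With all libraries no call was shared, as limma called 0 genes in the cultured cells (2 in activated B cells and 85 in plasmablasts at an unadjusted p under 0.05). The correlations were then lower, in the same order 0.106, 0.073 and 0.028.

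Genes that were higher in WT plasmablasts than in WT activated B cells were then followed in KO cells before the plasmablast stage. Without the 3 libraries the 343 higher genes had a median log2 difference of 0.417 in activated KO cells, 339 of them positive (adjusted p = 2.44e-78, and adjusted p = 0.0159 with an estimated correlation). The 672 lower genes had a median of -0.201 (adjusted p = 6.21e-16, and adjusted p = 0.123 with an estimated correlation). The lists share the WT activated libraries with this comparison, so a shift of many genes in those libraries could move both medians. In 50 simulations of unchanged groups the medians were 0.026 (0.009 to 0.05) and -0.03 (-0.049 to -0.017). The simulated lists held 379 and 728 genes at the median, and these ranges need not cover such a shift. Lists were also taken from the stages in KO cells, which share the KO activated libraries instead. Noise in those libraries would move these medians the opposite way, down for the higher genes and up for the lower genes. Their medians were 0.497 (144 of 159 positive) and -0.091 (177 of 469 positive). With all libraries the lists from WT cells had medians of 0.161 and -0.026 for 31 and 132 genes. The simulated medians were 0.148 (0.087 to 0.225) and -0.109 (-0.146 to -0.063), but from longer lists, of 154 and 352.5 genes at the median, so they set no range for the measured ones. In naive KO cells the lists from all libraries were not called (median -0.127 for 18 measured higher genes, adjusted p = 0.106, and -0.074 for 126 measured lower genes, adjusted p = 0.0682). The lists made without the 3 libraries were not called there either. Their medians were -0.006 for 258 measured higher genes and -0.027 for 628 measured lower genes (camera, adjusted p = 0.915 for each).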

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

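The tests in this part were planned, except the fits without naive KO guide 1 library A or without 3 cultured libraries, which were chosen after the results were seen. No sample was tested for standing apart within its group, as all groups hold 2 or 3 libraries.

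The KO difference of naive cells differed between the guides in 3 lists by the test of the difference itself. G2/M genes were relatively higher with guide 2 (19 of 19 members positive, median 0.84, adjusted p = 0.000954, and adjusted p = 0.827 with an estimated correlation). Marginal zone genes were relatively lower with guide 2 (15 of 17 members negative, median -0.41, adjusted p = 0.000954, and adjusted p = 0.788 with an estimated correlation). Interferon-stimulated genes were relatively higher with guide 2 (24 of 33 positive, median 0.28, adjusted p = 0.00408, and adjusted p = 0.788 with an estimated correlation). Without naive KO guide 1 library A 5 lists were called. WT cells of the guide 2 arm differed from those of the guide 1 arm by a median of 0.40 in marginal zone genes and -0.60 in G2/M genes. These WT differences enter the difference between the guides with the opposite sign. The guide and the arm, whose WT cells also differed in Xist and Y-linked genes, cannot be separated in this design.

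The KO difference differed between plasmablasts and activated B cells in 4 lists when all libraries were used. These were G2/M (median -0.76, adjusted p = 1.94e-05), oxidative phosphorylation (median -0.49, adjusted p = 0.000287), unfolded protein response (median -0.60, adjusted p = 0.000287) and plasma cell programme (median -0.57, adjusted p = 0.00334), each with adjusted p = 0.971 with an estimated correlation, beside a median of all genes of -0.127 (-0.019 with quantile normalization). The list medians with quantile normalization were, in the same order, -0.46, -0.11, -0.15 and -0.26. Without the 3 libraries the unfolded protein response (median -0.37, adjusted p = 1.15e-11), plasma cell programme (-0.53, 2.95e-11) and G2/M lists (-0.16, 0.0229) were called lower, with adjusted p = 0.329, 0.329 and 0.67 with an estimated correlation, and oxidative phosphorylation was not called (0.855).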

How the results depend on the processing

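Library weights and the fits without named sets of libraries were chosen after seeing the data, and the other alternatives were planned. All 10 counts of called genes stayed within 1.5 times with median-ratio scaling and with no filter. Named genes kept direction and side of the threshold in 107 of 108 cases with median-ratio scaling, 104 of 108 with no filter, 104 of 108 with quantile normalization, 100 of 100 at RPKM of 5, 94 of 108 with a pseudocount of 0.1 and 83 of 103 with the block, counting genes with a value. The causes of the following changes were not tested unless stated. With library weights limma called 399 genes in naive cells of both guides, 178 with guide 1, 59 with guide 2, 329 in activated B cells, and 4619 and 4374 between the stages in WT and KO. A pseudocount of 0.1 gave 60 with guide 1 and 0 with guide 2 (408 at an unadjusted p under 0.05), and the block 47, 0 (386 at an unadjusted p under 0.05) and 192 between the KO stages. The block cannot be fitted between the WT arms, whose letters are nested in the arms. With only the groups of a contrast in the fit, which leaves fewer samples to estimate the spread, the counts were 0 with guide 1 (882 at an unadjusted p under 0.05), 55 with guide 2, 9 between the WT arms, and 3132 and 15 between the stages in WT and KO. A filter at RPKM of 5 left 2 genes between the WT arms, as it tests fewer genes. Quantile normalization gave 369 and 565 between the stages in WT and KO. Without naive KO guide 1 library A guide 2 had 35 calls. Without the m3 activated libraries there was 1 call in activated B cells, 1 in plasmablasts and 59 between the KO stages. Without these and plasmablast KO library 3 there were 70, 7, 3 in the difference between stages, and 4565 and 3318 between the stages in WT and KO. Without plasmablast KO library 3 alone, 3303 genes were called between the WT stages, a comparison that shares no library with it, through the spread shared by all groups. Over each library left out in turn the counts ranged from 73 (without WT guide 2 B) to 387 (without KO guide 1 A) for both guides, from 0 (without WT guide 1 C) to 371 (without KO guide 1 B) for guide 1, 0 to 0 for guide 2, 0 to 0 for the difference between guides, 5 to 6 between the WT arms, 0 to 0 in activated B cells, 0 to 0 in plasmablasts and 0 to 0 for the difference between stages, from 0 (without WT plasmablast 2) to 186 (without the activated m3 library labelled WT) between the WT stages and from 22 (without activated KO m2) to 3033 (without plasmablast KO 3) between the KO stages. Named calls were lost most often without WT guide 2 B (22), KO guide 2 A (21) and WT guide 2 C (19).

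With an estimated correlation camera called 0 lists in 9 comparisons and 1 between the WT stages, against 9, 7, 8, 3, 5, 1, 6, 4 and 13 and then 14 with the preset correlation. Fry called 0 lists for guide 1, guide 2, their difference, the WT arms, activated B cells, plasmablasts and the difference between stages. Quantile normalization gave 8 lists between the WT arms, 6 in activated B cells and 1 in plasmablasts. Without naive KO guide 1 library A 5 lists differed between the guides. Without plasmablast KO library 3 the counts were 2 in activated B cells, 11 in plasmablasts and 7 for the difference between stages, and without the 3 libraries 8, 11 and 14. Shared calls were 9 between naive and activated B cells, 4 between naive cells and plasmablasts and 2 between activated B cells and plasmablasts without the 3 libraries, and 1 between the guides without Irf8 and Thy1 and 19 without naive KO guide 1 library A. The genes higher in plasmablasts had a median of 0.082 in naive KO cells when taken from KO cells, against -0.127, neither called. In activated B cells with all libraries their median of 0.161 and that of the lower genes, -0.026, were not called with an estimated correlation. In plasmablasts Il10 went from -0.08 to 1.56 and Bcl2a1b from -0.05 to 1.02 without the 3 libraries.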

Other observations

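Chosen only after their results were seen were the tests of the m3 libraries on all genes and on Thy1, of other cell types, of the WT arms as an axis and of all genes against Fcer2a, and every fit without named libraries.

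Further lists were called lower in WT plasmablasts than in WT activated B cells, and none of these calls held with an estimated correlation. B cell receptor genes were called lower (24 members, 4 fell, 7 adjusted over the list alone, median -0.56, adjusted p = 4.87e-05, and adjusted p = 0.32 with an estimated correlation), as were costimulation genes (18, 4 fell, 7 adjusted over the list alone, -0.58, 0.00115, and adjusted p = 0.228 with an estimated correlation), the BCL2 family (13, 3 fell, 7 adjusted over the list alone, -1.04, 0.00137, and adjusted p = 0.32 with an estimated correlation) and Toll-like receptor genes (22, 0 fell, 6 adjusted over the list alone, -0.62, 0.00156, and adjusted p = 0.228 with an estimated correlation). Interferon-gamma-inducible GTPases (12, 2 fell, 4 adjusted over the list alone, -0.78, 0.0024, and adjusted p = 0.228 with an estimated correlation) and trafficking receptors (20, 2 fell, 5 adjusted over the list alone, -0.45, 0.0242, and adjusted p = 0.228 with an estimated correlation) were lower too. MYC targets were lower without a called member (21, 3 adjusted over the list alone, -0.60, 0.0116, and adjusted p = 0.631 with an estimated correlation). Of the lists of other cell types, stromal and endothelial cells (1 member, which fell, -1.91, 0.0122, and adjusted p = 0.202 with an estimated correlation) and erythroid cells (4, 0 fell, 1 adjusted over the list alone, -1.10, 0.0242, and adjusted p = 0.32 with an estimated correlation) were called lower in WT. Erythroid cells were called lower in KO plasmablasts too (4, 1 fell, 3 adjusted over the list alone, -1.65, 0.0239, and adjusted p = 0.445 with an estimated correlation). Between the WT stages the trafficking list and the stromal and endothelial list were not called without the 3 libraries left out above. Without the 3 libraries, 25 of 27 unfolded protein response genes rose (median 1.09) and 19 of 22 plasma cell genes rose (median 1.33), the same lists in which 0 and 1 were called with all libraries. In KO cells without the 3 libraries 24 of 27 and 17 of 22 rose (medians 0.69 and 0.89), beside a median of all genes of -0.159 in WT and -0.101 in KO. The activated WT group with all libraries includes the m3 library labelled WT.

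All naive libraries of the guide 1 arm held Xist at 3.39 to 6.28 RPKM with Eif2s3y listed at 0, and those of the guide 2 arm held Eif2s3y at 31.0 to 38.8 and Ddx3y at 18.1 to 27.8 with Xist at most 0.047. All cultured libraries held Eif2s3y, at 6.61 to 26.0 RPKM. These genes were chosen after their values were seen.

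In the m3 activated B cell libraries Thy1 and Irf8 went against the labels. An opposite response to the knockout is argued against by Thy1, the marker of the sort, which was 277 times as high in the m3 library labelled WT as in the m3 library labelled KO. Exchanged labels are a candidate explanation, since across 9984 genes the m3 difference correlated at r = -0.665 with the mean difference of m1 and m2, which correlated at 0.437 with each other (genes are not independent replicates). Genes called higher minus genes called lower in naive KO cells differed by a median of -0.443 in m3, against 0.396 in m1 and 0.224 in m2. At which step an exchange might have occurred was not tested, and the labels were used as given.

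Marginal zone genes were called higher as a list in naive KO cells (adjusted p = 0.217 with an estimated correlation). Library A of guide 1 as the sole source is argued against by the median of 0.8 without it (adjusted p = 3.32e-17, and adjusted p = 0.253 with an estimated correlation). Cells of other types that pass a sort for B220 without CD11b, F4/80 and Thy1.2 stay open, since 0 of 6 lists with measured members were higher in KO, but these held 1 to 10 members, and Prf1 of the natural killer list rose (log2 difference 1.26, adjusted p = 0.00775), as did Trem1, a receptor of myeloid cells (1.56, adjusted p = 0.00313). More marginal zone and fewer follicular cells among the sorted KO cells stays open, since the KO difference correlated across 10130 genes at r = 0.383 with the difference between the WT arms, but at 0.125 to 0.32 when no WT library was in both, and at up to 0.333 in size in 9 other splits of the WT libraries. Whether fewer follicular cells account for all genes that fell stays open too, with a direct effect of Irf8 loss, untested, since 23.3% of the genes called lower (20 of 86) had a KO to WT ratio below the 0.488 of Fcer2a with libraries apart, but these were chosen as called, and over all genes limma called 1, Wfdc17, lower than Fcer2a (one-sided, adjusted p = 0.0292).

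Plasmablast KO library 3 correlated with the other cultured libraries at a median of 0.477. Low depth alone is argued against by plasmablast KO libraries 1 and 2, whose medians were 0.949 and 0.948 in full. Thinned to the same number of reads they fell to 0.781 and 0.796, so lower depth reduced the correlation, but not to 0.477. The thinned libraries had 3255 and 3413 genes at 0 and library 3 had 1984. No biological explanation was tested. Loss or uneven amplification of RNA was not tested either, and would have to account for fewer genes at 0 than in the thinned libraries.

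Splits of the same libraries were counted for each comparison of at least 3 against 3. For naive cells of both guides, 1 of 100 splits within the arms, the real one, gave as many calls, 191 against 42 in the highest other, so a chance split is an unlikely account. For the difference between guides 100 of 100 splits gave at least the real 0 calls (479 genes at an unadjusted p under 0.05 in limma), and the highest other, 191, was the split that exchanges KO and WT within 1 arm. With 10 splits, too few for a share under 0.05, the real and highest other counts were 113 and 0 for guide 1, 3 and 0 for guide 2, 5 and 2 between the WT arms, 0 and 1 in activated B cells (all 10 splits gave at least 0) and 344 and 2 between the KO stages. Without plasmablast KO library 3, the split of activated B cells that exchanges the m3 libraries called 472 genes and the real and all other splits 0, which points to a structure of the samples along that exchange.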
